A study of Homo sapiens with 18 samples.

How the data were processed

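The deposited per-sample tables held Salmon output, with the authors' estimated read count, TPM and effective length of 252048 transcripts per the file headers. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.10 and quantified with Salmon 1.10.0, and the genome is given as hg19. Of the transcript identifiers 80.0% occur in GENCODE 29, and positions are given in GRCh38 from GENCODE 29, which covers 57804 of the 62749 genes. Per the labels, RNA was extracted with a PureLink kit and 500 ng of total RNA entered TruSeq stranded mRNA libraries. The cell line field of the labels ends in a number that rises by 1 from sample to sample, while the growth protocol names MDA-MB-231 for all, so 1 line was assumed.

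The deposited estimated counts were summed over transcripts to genes and rounded, since 32.5% of the transcript values were not whole numbers. The deposited series table of expected counts, summed in the same way, gave the same values with a largest difference of 0.0. CPM was computed here from the deposited estimated counts with TMM-scaled library sizes. For single transcripts it was computed with library totals, without TMM scaling. Gene symbols were taken from the files, and 62231 gene identifiers matched the reference names when the version was left off.

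Genes with low counts were removed with filterByExpr, which left 19252 genes. All 18 libraries entered 1 edgeR 4.0.16 fit with TMM scaling, a mean per group and the quasi-likelihood test (R 4.3.3), with Benjamini-Hochberg adjustment within each comparison. There were 10 comparisons, 6 main and 4 secondary, and adjustment was not made across comparisons. The common biological coefficient of variation was 4.87% and the median prior degrees of freedom were 5.2. The 27 gene lists were tested on log2 CPM (prior count 2) with camera from limma 3.58.1, a competitive test with an inter-gene correlation preset at 0.01, and with Benjamini-Hochberg adjustment over the lists of a comparison. Beside it stood camera with an estimated correlation, and fry, which does not compare a list with other genes. DESeq2 1.42.0 gave an alternative test. The threshold for every adjusted p was 0.05.

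The lists covered purine synthesis, purine salvage, pyrimidine and deoxynucleotide synthesis, ribosome biogenesis, ribosomal proteins, PARP and ADP-ribosylation, NAD metabolism, base excision repair, homologous recombination, damage signalling with end joining, p53 targets, DNA replication, G2/M, the ATF4 response, the unfolded protein response, interferon, NF-kB, cholesterol synthesis, hypoxia with glycolysis, the nuclear-encoded respiratory chain, mitochondrially encoded genes, NRF2 targets, replication histones, mesenchymal genes, YAP targets, and markers of luminal or epithelial and of blood or endothelial cells. They were written from background knowledge.

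The groups, comparisons, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. The rule took IMPDH2 and IMPDH1, the 10 higher and 10 lower coding genes with the largest fold among those that passed, with an average log2 CPM of at least 1 and no overlap between groups, and up to 4 members of each called list with the smallest adjusted p in the direction of the list. Where this gave more than about 30 genes, the text gives the first of each rank. A few genes that the rule takes are not reported here. Added after the data were examined were PARP1, coding genes alone as an alternative, IMPDH2 with the overlapping locus, and lists with the median of each gene's chromosome window subtracted. The alternatives fixed beforehand were DESeq2 size factors, no filter on low counts, the DESeq2 Wald test, a replicate block, a fit of the 6 compared samples alone, an offset for average transcript length, the series count table, a minimum log2 fold change of 1, each library left out in turn, and the other list tests.

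A self-test used simulated counts with 1 mean per gene over all 18 libraries and the fitted spread. Some genes were then changed in KO, far fewer than differed between the real KO and WT. With edgeR it recovered 74.6% of 67 genes changed by a log2 of 0.5, 97% of 67 at 1 and 95.5% of 66 at 2. Of the calls 5.2% were false. DESeq2 recovered 74.6%, 98.5% and 95.5% with 8.1% false. Camera called the list of 30 genes shifted by 0.5 and 0 of 26 unshifted lists, and fry called 1 of 26. The simulated genes were independent of one another and the lists were random, so this says nothing about correlated members of real lists.

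Simulations of shared controls were run 10 times with the fitted means and spread. Chromosome windows held at least 50 neighbouring coding genes, 224 windows and 11703 genes in all, and were set against 1000 shuffles of gene positions. The replicate check used genes with a mean count of at least 10. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 joined the tables and drew the plots. The raw reads were not analysed here.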

Results

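Messenger RNA was sequenced from MDA-MB-231, a triple-negative breast cancer cell line, in 18 libraries of 6 groups with 3 libraries each. The groups were unedited cells (WT), cells with a knockout of IMPDH2 (KO), KO cells grown with 400 µM guanosine, and KO cells given back IMPDH2 in an unlocalised, a nuclear or a cytosolic form. IMPDH2 is inosine monophosphate dehydrogenase, the rate-limiting enzyme of guanine nucleotide synthesis, and guanosine can supply the same nucleotides by salvage. Estimated counts totalled 45.9e6 to 63.3e6 per library, and 19252 genes passed the filter on low counts. The labels do not say whether the 3 libraries of a group came from separate cultures, so every p measures the spread between these samples only. Levels are TMM-scaled CPM, counts scaled to a common library size, except that single transcripts are in CPM of library totals. Each ± is an SD over n = 3 libraries, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 in edgeR's quasi-likelihood test. Each gene named among the largest changes had no overlap between the 3 values of one group and the 3 of the other, which chance gives for 10% of genes. The share of counts on mitochondrially encoded genes was 5.18% ± 0.03 in WT and between 7.41% ± 0.19 and 7.82% ± 0.37 in the 5 knockout-derived groups. List members named as examples moved in the direction of their list. Intervals and floors come from counts summed over the 3 libraries of a group. They cover counting error only and leave out the spread between libraries. The reads carried no molecular identifiers.

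IMPDH2 (ENSG00000178035.13, minus strand of chromosome 3, 49024325 to 49029408 in GRCh38) was measured in every sample first, because it checks the labels. Its level was 318.8 ± 0.56 CPM in WT, 41.6 ± 0.57 in KO and 22.1 ± 0.11 in KO with guanosine, so 13.1% and 6.9% of the WT level remained. The unlocalised form brought it to 532.2 ± 10.43 CPM (166.9% of WT), the nuclear form to 297.4 ± 12.63 (93.3%) and the cytosolic form to 378.7 ± 13.88 (118.8%). The coding transcript IMPDH2-201 alone stood at 6.1% of WT in KO (13.48 ± 12.08 against 220.24 ± 10.37 CPM, with 0, 23.33 and 17.12 in the 3 KO libraries), and at 231.8% with the unlocalised, 127% with the nuclear and 163.6% with the cytosolic form. These transcript values used library totals without TMM scaling, so their percentages are not on the same scale as those of the gene. With the locus that overlaps IMPDH2 and QRICH1 added, the 3 forms stood at 193.7%, 114.7% and 145.6%, so the nuclear form lay below or above WT depending on the measure. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, IMPDH2 fell in KO against WT (log2 fold change -2.94 ± 0.033 SE, adjusted p = 1.34e-20) and rose with each form against KO, by 3.68, 2.84 and 3.19 on the log2 scale for the unlocalised, nuclear and cytosolic form. IMPDH2 overlaps a readthrough-like locus that also spans its neighbour QRICH1, so its reads could be divided between annotations. IMPDH1 (ENSG00000106348.19, chromosome 7, 128392277 to 128410252 in GRCh38), the paralog with the same enzyme activity, ranged from 43.7 ± 1.5 CPM in WT to 53.9 ± 0.45 with the nuclear form. It was 1.16-fold higher in KO than in WT (adjusted p = 1.08e-05, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment).

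**Figure D1:**
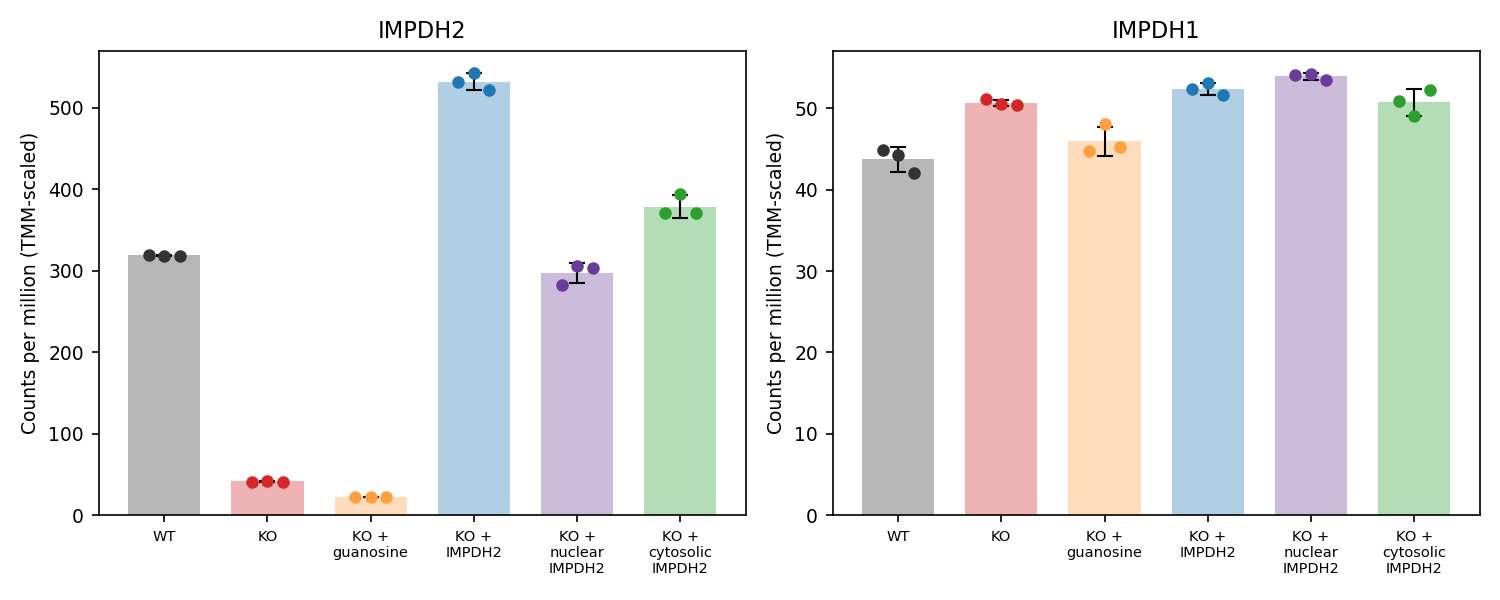
IMPDH2 and IMPDH1 in TMM-scaled CPM on the y axes, by group on the x axes. Points are the 3 libraries of a group, bars their mean and error bars the SD: IMPDH2 was 318.8 in WT, 41.6 in KO and 22.1 in KO with guanosine, and the 3 reconstituted lines stood at 297.4 to 532.2.

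Principal component 1 held 42.6% of the variance of log2 CPM and parted WT from all knockout-derived libraries, and component 2 held 10.5% and parted KO from the other knockout-derived groups.

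**Figure D2:**
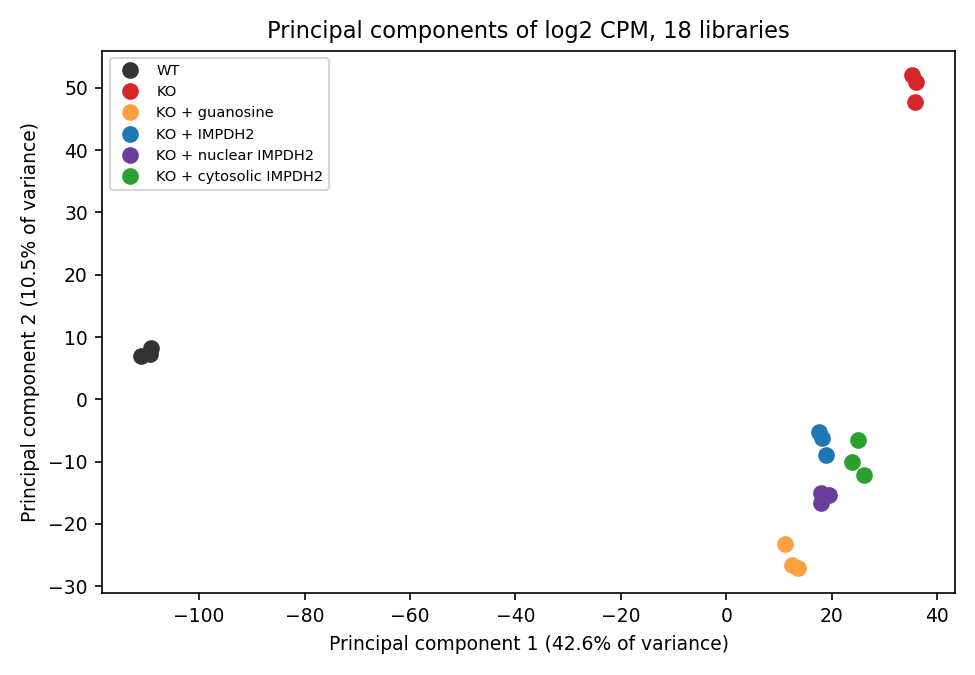
The 18 libraries on principal components 1 and 2 of log2 CPM, with 42.6% and 10.5% of the variance, 1 point per library and 1 colour per group. WT stands apart on component 1, and KO stands apart from the guanosine and reconstituted groups on component 2.

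The comparison of KO with WT asks what differed between the knockout cells and WT, from IMPDH2 loss or otherwise. Lower in KO were 30 of 30 mitotic, 27 of 33 replication, 21 of 22 sterol, 18 of 26 hypoxia and glycolysis, 16 of 20 oxidative stress and 21 of 26 mesenchymal genes, and higher were 23 of 29 interferon-stimulated genes and 13 of 13 mitochondrial transcripts. None of these lists was called with an estimated correlation, where camera gave adjusted p from 0.163 to 0.466. All 30 tested mitotic genes fell, among them PLK1, a kinase of mitotic entry (34.1 ± 0.172 CPM in KO, 150 ± 2.93 in WT, 4.39-fold lower), and BIRC5, which encodes survivin (3.16-fold lower). BST2, an interferon-induced factor that tethers virions, was 3.71-fold higher. Some genes were lost or gained outright: PHGDH, which catalyses the first step of serine synthesis, had 65 ± 2.03 CPM in WT and 0 counts in KO, at least 3750-fold lower against a floor of 3 counts over the group. In all, 13996 of 19252 genes changed, 6912 higher and 7084 lower, and 4376 of them by at least 2-fold (2457 higher, 1919 lower). For coding genes alone 4991 were higher and 6300 lower, and of the coding genes among the 4376 changed by at least 2-fold 1237 were higher and 1482 lower. The TMM scaling moved the median log2 fold change of all genes by 0.161 against scaling by library totals, and changes are given relative to it.

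The largest gains in KO were NALF2, an auxiliary subunit of a sodium leak channel (2.77 ± 0.559 CPM in KO, 0 counts in WT, at least 139-fold higher), and ITM2A, a membrane protein, with 1865 counts in KO against 2 in WT, a ratio of 809 with a 95% counting interval from 224 to 6680. Next came PGM5, a relative of phosphoglucomutase found at cell junctions (32.4 ± 1.78 against 0.2 ± 0.0172 CPM, 160-fold), CYP7B1, an oxysterol hydroxylase (4.17 ± 0.614 against 0.0267 ± 0.0232 CPM), and EPB41L3, a membrane skeleton protein (80.9 ± 2.2 against 0.664 ± 0.108 CPM, 121-fold). Besides PHGDH, the largest losses included ARHGEF10 (23.5 ± 0.471 CPM in WT, 0 counts in KO, at least 1360-fold lower), MXRA8, an adhesion protein (ratio 2670, interval 738 to 22000), and COL4A5, a chain of collagen IV (ratio 1800, interval 497 to 14800). TUBA3C, MAGEA12 and MAGEA3 were at or near 0 in KO too, but they share sequence with paralogs, so their counts are uncertain. Some of these changes did not return with rescue. In the groups given guanosine or IMPDH2, NALF2 stood at 2.36 to 3.07 CPM and ITM2A at 9.52 to 15.5 CPM. ARHGEF10 had 7 counts in all knockout-derived libraries together. The levels of the other genes named here after rescue are not given.

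Cell cycle genes moved down together in KO. None of the 30 G2/M genes was higher and 30 were lower, with 0 and 30 also when adjusted over the list alone, and their median log2 fold change was -1.55 (camera adjusted p = 7.57e-16, adjusted p = 0.163 with an estimated correlation). KIF20A, a mitotic kinesin, was 5.28-fold lower, and CCNB1, which encodes cyclin B1, 2.89-fold lower. Of 33 DNA replication genes, 27 were lower, 3 higher and 3 did not pass, with 27 and 3 when adjusted over the list alone (camera adjusted p = 8.36e-06, adjusted p = 0.163 with an estimated correlation). MCM4, a subunit of the replicative helicase, fell from 198 ± 4.02 to 95 ± 2.44 CPM, and ORC1, an origin recognition subunit, was 2.42-fold lower. Of 18 pyrimidine and deoxynucleotide genes, 12 were lower, 2 higher and 4 did not pass, with 12 and 2 when adjusted over the list alone (camera adjusted p = 0.0289, adjusted p = 0.466 with an estimated correlation). TYMS, thymidylate synthase, was 2.57-fold lower, and RRM2, a subunit of ribonucleotide reductase, 1.84-fold lower. This list was no longer called after the median of each gene's chromosome window was subtracted (adjusted p = 0.184).

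Metabolic lists fell as well. Of 22 sterol genes 21 were lower and 1 higher, in the same numbers when adjusted over the list alone (camera adjusted p = 1.03e-07, adjusted p = 0.163 with an estimated correlation). An example was FDPS, farnesyl diphosphate synthase (86.1 ± 0.811 against 202 ± 2.31 CPM, 2.35-fold lower). Of 26 hypoxia and glycolysis genes 18 were lower, 3 higher and 5 did not pass, or 19 lower and 4 higher when adjusted over the list alone (camera adjusted p = 0.000574, adjusted p = 0.441 with an estimated correlation). ENO1, a glycolytic enolase, fell from 3220 ± 53 to 868 ± 8.21 CPM and the glucose transporter gene SLC2A1 was 2.72-fold lower. Of 20 NRF2 targets 16 were lower and 4 higher, in the same numbers when adjusted over the list alone (camera adjusted p = 0.00263, adjusted p = 0.248 with an estimated correlation). An example was TKT, which encodes transketolase (190 ± 6.64 against 463 ± 5.85 CPM, 2.44-fold lower). Of 29 ATF4 response genes 21 were lower, 7 higher and 1 did not pass, with 21 and 7 when adjusted over the list alone (camera adjusted p = 0.0034, adjusted p = 0.163 with an estimated correlation). PSAT1, another enzyme of serine synthesis, was 2.18-fold lower and DDIT4, an inhibitor of mTORC1, 5.23-fold lower. The median of this list was -0.58 with PHGDH at its fitted value and also with PHGDH at its bound.

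Matrix, epithelial and interferon lists and the mitochondrial transcripts were called too. Of 26 mesenchymal genes 21 were lower, 2 higher and 3 did not pass, with 21 and 2 when adjusted over the list alone (camera adjusted p = 7.87e-05, adjusted p = 0.163 with an estimated correlation). TGFBI, a matrix adhesion protein, was 6.05-fold lower and ITGA5, integrin alpha 5, 2.07-fold lower. Of 17 luminal and epithelial markers 10 were lower, 2 higher and 5 did not pass, with 10 and 2 when adjusted over the list alone (camera adjusted p = 0.0289, adjusted p = 0.163 with an estimated correlation). Examples were CLDN4, a tight junction claudin (5.35 ± 0.251 against 52.8 ± 1.35 CPM), and KRT18, a simple epithelial keratin (2.77-fold lower). Of 29 interferon-stimulated genes 23 were higher, 5 lower and 1 did not pass, with 23 and 5 when adjusted over the list alone and a median log2 fold change of 0.85 (camera adjusted p = 0.000345, adjusted p = 0.171 with an estimated correlation). IRF9, a subunit of the ISGF3 transcription factor, was 2.34-fold higher, and IFI27, an interferon-induced protein, 2.88-fold higher. All 13 mitochondrially encoded genes were higher, also when adjusted over the list alone (camera adjusted p = 0.000579, adjusted p = 0.466 with an estimated correlation). An example was MT-ND1, a subunit of complex I (1.88-fold). The mitochondrial share of counts was 7.72% ± 0.17 in KO against 5.18% ± 0.03 in WT. PARP1, a poly(ADP-ribose) polymerase described because the series title names it, had 271.4 ± 9.16 CPM in KO and 250.9 ± 1.43 in WT (1.08-fold higher, adjusted p = 0.000754 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and with an offset for transcript length its log2 fold change was 0.01 and no longer passed.

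The other 16 lists were not called by camera in KO against WT, with adjusted p from 0.138 to 0.901. Counts of higher and lower members were 8 and 12 of 21 for purine synthesis, 9 and 8 of 19 for purine salvage, 12 and 12 of 30 for ribosome biogenesis, 18 and 17 of 44 for ribosomal proteins, and 7 and 11 of 23 for PARP enzymes and ADP-ribosylation. They were 8 and 7 of 18 for NAD metabolism, 10 and 8 of 21 for base excision repair, 6 and 13 of 25 for homologous recombination, 9 and 16 of 30 for damage signalling and end joining, 11 and 14 of 30 for p53 targets, and 4 and 10 of 18 for the unfolded protein response. They were 14 and 7 of 24 for NF-kB targets, 8 and 17 of 35 for the nuclear-encoded respiratory chain, 6 and 5 of 12 for replication histones, 7 and 11 of 21 for YAP targets, and 2 and 3 of 8 for blood and endothelial markers. Adjusted over the list alone, 1 more gene was lower for ribosomal proteins and for damage signalling, 1 more was higher for PARP enzymes and for base excision repair, and the other counts stayed. Median, mean and camera direction did not all share a sign for ribosome biogenesis, NAD metabolism, p53 targets, replication histones, and blood and endothelial markers. No list was called with an estimated correlation, and 26 of 27 were called by fry, which asks whether the members of a list move one way on balance without comparing them with other genes.

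Neighbouring genes moved together in KO against WT. Medians of log2 fold change over 224 windows of at least 50 neighbouring coding genes had an SD of 0.301, against at most 0.107 in 1000 shuffles of gene positions. The lowest medians were -1.11 at 6221193 to 13825079, -1.09 at 944204 to 6221299 and -1.09 at 15152532 to 22921500 on chromosome 1, and -1.08 at 47107403 to 80147523 on chromosome 18 (GRCh38). With window medians subtracted, the list medians were -1.38 for G2/M, -0.48 for DNA replication, -0.61 for sterol synthesis, -0.48 for glycolysis, -0.66 for NRF2 targets, -0.91 for mesenchymal genes and 1.04 for interferon-stimulated genes. Knockout and clone differ together between these groups, and this comparison alone holds no value that separates them.

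The comparison of KO with and without guanosine asks what guanine nucleotide salvage changed in the absence of IMPDH2. With guanosine 30 of 30 mitotic, 33 of 33 replication and 20 of 25 recombination genes rose, and 25 of 29 interferon-stimulated and 15 of 24 inflammatory genes fell. With an estimated correlation the recombination and inflammatory lists were no longer called (camera adjusted p = 0.0667 and 0.199). CDCA3, which promotes mitotic entry, rose from 14.7 ± 0.799 to 50.7 ± 2.11 CPM. The largest rises included NEGR1, a neuronal adhesion protein (16.9 ± 0.862 against 3.31 ± 0.104 CPM, 5.09-fold), B4GALNT1, a ganglioside synthase (5.06-fold), DMBT1, a scavenger receptor (4.73-fold), PDE7B, a cAMP phosphodiesterase (4.22-fold), and MALL, a membrane raft protein (3.49-fold). The largest falls were SERPIND1, the thrombin inhibitor heparin cofactor II (2.44 ± 0.143 against 18.4 ± 0.925 CPM, 7.53-fold), and IL2RG, the common gamma chain of interleukin receptors (6.48-fold). PTPRR, a tyrosine phosphatase, was 5.46-fold lower, ADGRF4, an adhesion receptor, 5.23-fold lower, and PTGS2, the prostaglandin synthase COX-2, 4.85-fold lower. In all 10882 genes changed, 5256 higher and 5626 lower, and 1481 by at least 2-fold (483 higher, 998 lower). The larger side turned with DESeq2 size factors (5510 higher, 5339 lower) and for coding genes alone (4860 higher, 4370 lower). IMPDH2 fell further, by 0.91 on the log2 scale, and IMPDH1 was 1.1-fold lower. With an offset for transcript length the IMPDH1 call ended (log2 fold change -0.07, adjusted p = 0.415 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). PARP1 rose from 271.4 ± 9.16 to 405.7 ± 0.822 CPM (1.49-fold).

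All 30 G2/M genes rose with guanosine, with a median log2 fold change of 1.25 (camera adjusted p = 6.95e-26, adjusted p = 0.024 with an estimated correlation). Members included BIRC5 (3.1-fold), PLK1 (3.24-fold) and CCNB1 (2.52-fold). All 33 DNA replication genes rose too, and both lists kept all their members when adjusted over the list alone (camera adjusted p = 2.53e-18, adjusted p = 0.0131 with an estimated correlation). Examples were MCM5, a helicase subunit (1.64-fold), and CDC45, which activates the helicase (1.95-fold). Of 25 homologous recombination genes 20 rose, 1 fell and 4 did not pass, with 20 and 1 when adjusted over the list alone (camera adjusted p = 2.75e-08, adjusted p = 0.0667 with an estimated correlation). RAD54L, a motor protein of strand exchange, was 2.36-fold higher and the Fanconi anaemia gene FANCI 1.85-fold higher. Of 30 damage signalling genes 15 rose, 7 fell and 8 did not pass, with 15 and 7 when adjusted over the list alone (camera adjusted p = 0.0467, adjusted p = 0.685 with an estimated correlation). The list included CLSPN, which encodes claspin (1.85-fold), and WEE1, a checkpoint kinase (1.56-fold). Of 18 pyrimidine and deoxynucleotide genes 10 rose, 3 fell and 5 did not pass, with 10 and 3 when adjusted over the list alone (camera adjusted p = 0.00639, adjusted p = 0.38 with an estimated correlation). Members included RRM2 (2.43-fold) and TYMS (2.37-fold).

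Interferon-stimulated genes fell with guanosine: 25 of 29 were lower, 1 higher and 3 did not pass, or 27 lower and 1 higher when adjusted over the list alone (camera adjusted p = 2.08e-09, adjusted p = 0.0265 with an estimated correlation). OASL, a relative of oligoadenylate synthase, was 3.15-fold lower and IRF9 1.66-fold lower. Of 24 NF-kB targets 15 fell, 2 rose and 7 did not pass, with 15 and 2 when adjusted over the list alone (camera adjusted p = 0.000126, adjusted p = 0.199 with an estimated correlation). TNFAIP3, an inhibitor of NF-kB signalling, was 1.84-fold lower, and PTGS2 is a member too. Of 22 sterol genes 21 rose and 1 did not pass, with 21 when adjusted over the list alone (camera adjusted p = 3.75e-09, adjusted p = 0.0977 with an estimated correlation). Examples were EBP, a sterol isomerase (1.84-fold), and FDPS (1.55-fold). Of 21 YAP targets 15 rose, 2 fell and 4 did not pass, or 16 and 2 when adjusted over the list alone (camera adjusted p = 9.29e-05, adjusted p = 0.0131 with an estimated correlation). The list included AMOTL2, an angiomotin (1.7-fold), and NT5E, an ectonucleotidase that makes adenosine and other nucleosides (1.84-fold). Of 13 mitochondrially encoded genes 10 rose, 1 fell and 2 did not pass, with 10 and 1 when adjusted over the list alone (camera adjusted p = 0.0214, adjusted p = 0.744 with an estimated correlation). An example was MT-ND2 (1.31-fold). The mitochondrial share was 7.82% ± 0.37 with and 7.72% ± 0.17 without guanosine. The other 17 lists were not called (camera adjusted p 0.0596 to 0.989).

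**Figure D3:**
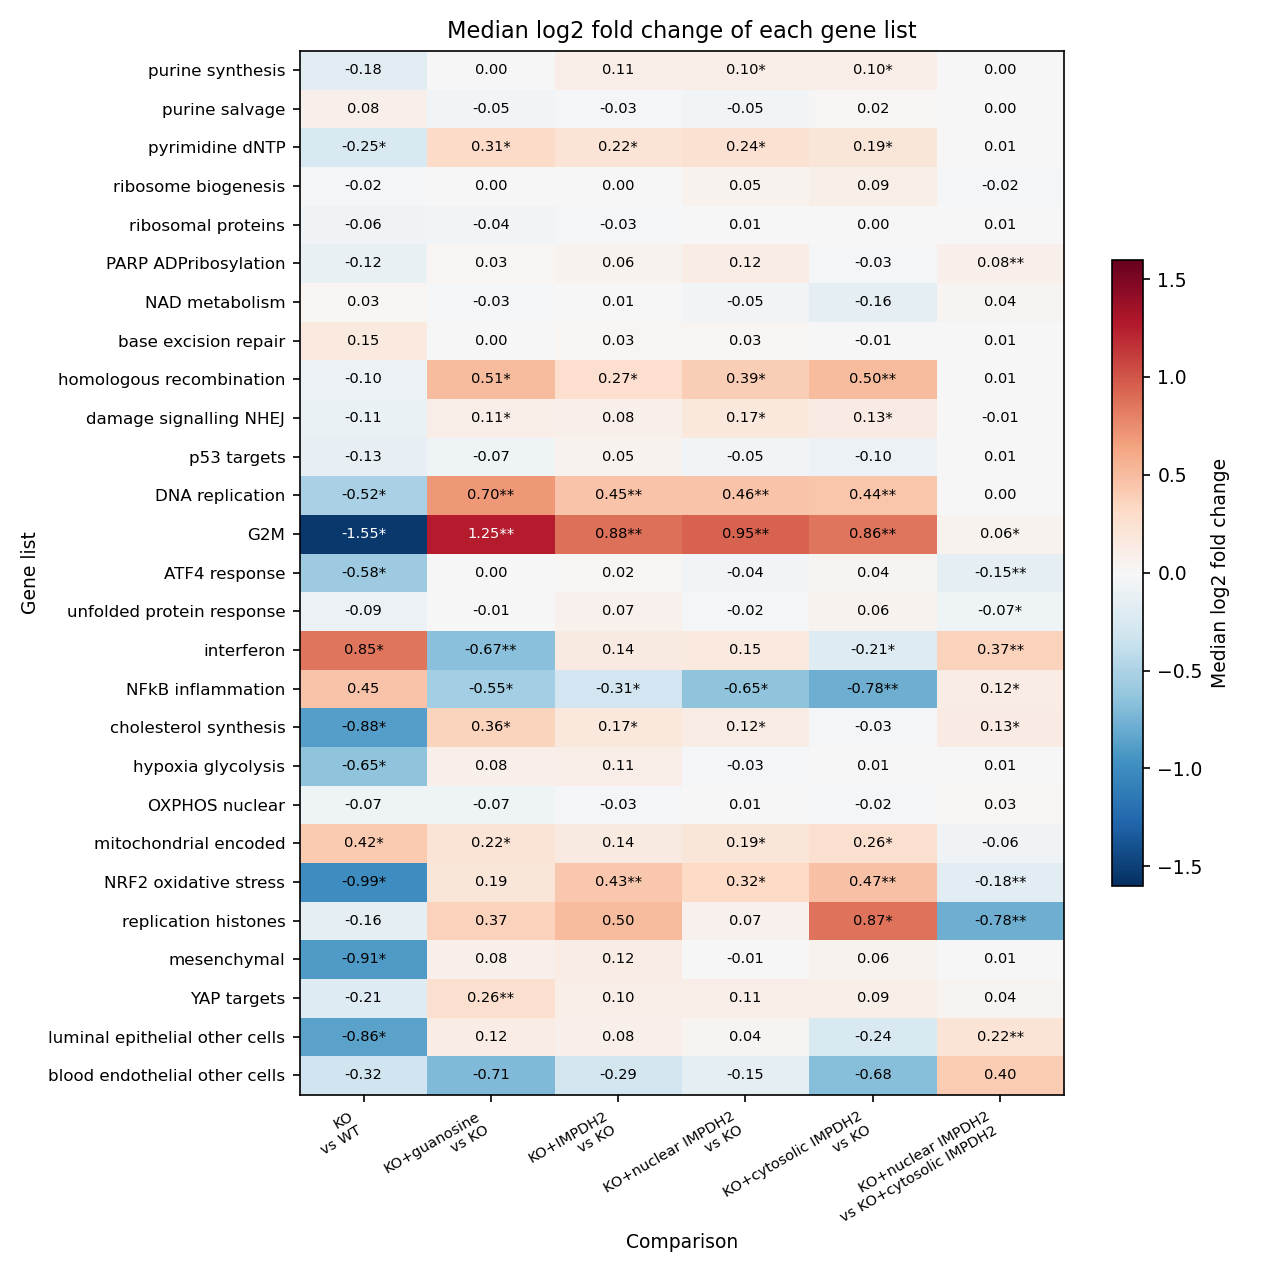
Median log2 fold change of the tested members of each of 27 gene lists (y axis) in 6 comparisons (x axis), as colour and number. A star marks a camera call and a pair of stars a call kept with an estimated correlation; G2/M genes stood at -1.55 in KO against WT and at 0.86 to 1.25 in the 4 comparisons against KO.

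The comparison of KO given back unlocalised IMPDH2 with KO asks what the enzyme restored. Of the lists, 30 of 30 mitotic, 32 of 33 replication, 21 of 25 recombination and 18 of 20 NRF2 target genes rose, and 14 of 24 NF-kB targets fell. With an estimated correlation the recombination and NF-kB lists were no longer called (camera adjusted p = 0.149 and 0.55). IL13RA2, a decoy receptor for interleukin 13, rose most among coding genes other than the locus that overlaps IMPDH2 (30.4 ± 1.14 against 1.16 ± 0.0491 CPM, 26.1-fold), followed by MALL (5.2-fold), NEGR1 (4.04-fold) and ENG, the TGF-beta coreceptor endoglin (3.22-fold). B4GALNT1 was 3.13-fold higher, HMMR, a hyaluronan receptor that acts at the spindle, 2.85-fold and CCDC69 2.79-fold higher. The largest falls included IL2RG (1.84 ± 0.117 against 16.4 ± 0.219 CPM, 8.86-fold), KISS1, which encodes kisspeptin (4.23-fold), EPHB1, an ephrin receptor (3.97-fold), and MDK, which encodes the growth factor midkine (15 ± 0.738 against 59.2 ± 3.23 CPM, 3.93-fold). MAGEA6, with close paralogs, was 12.2-fold lower and is uncertain. QRICH1 was 8.43-fold lower while the overlapping locus ENSG00000290315 was 67.6-fold higher, and both are uncertain because their annotations overlap. CACNA2D4 was 2.91-fold higher, but with an offset for transcript length its call ended. In all 9780 genes changed, 4944 higher and 4836 lower, and 955 by at least 2-fold (253 higher, 702 lower). With the length offset 6511 changed. IMPDH1 did not pass (log2 fold change 0.05 ± 0.032 SE, adjusted p = 0.235 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and PARP1 rose to 351.7 ± 2.53 CPM (1.3-fold).

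All 30 G2/M genes rose with IMPDH2, also when adjusted over the list alone, with a median log2 fold change of 0.88 (camera adjusted p = 6.52e-26, adjusted p = 0.0359 with an estimated correlation). Examples were BIRC5 (2.19-fold), PLK1 (2.43-fold) and CCNB1 (1.92-fold). Of 33 DNA replication genes 32 rose and 1 did not pass, and 33 rose when adjusted over the list alone (camera adjusted p = 1.41e-15, adjusted p = 0.0359 with an estimated correlation). The list included MCM5 (1.6-fold) and MCM4 (1.44-fold). Of 25 homologous recombination genes 21 rose, 2 fell and 2 did not pass, with 21 and 2 when adjusted over the list alone (camera adjusted p = 1.19e-06, adjusted p = 0.149 with an estimated correlation). Members included FANCA (1.67-fold) and RAD54L (1.59-fold). Of 18 pyrimidine and deoxynucleotide genes 11 rose, 3 fell and 4 did not pass, with 11 and 3 when adjusted over the list alone (camera adjusted p = 0.0124, adjusted p = 0.55 with an estimated correlation). Examples were RRM2 (1.77-fold) and TYMS (1.58-fold). Of 20 NRF2 targets 18 rose and 2 did not pass, with 18 when adjusted over the list alone (camera adjusted p = 9.93e-09, adjusted p = 0.0384 with an estimated correlation). NQO1, a quinone reductase, was 2.17-fold higher and TXNRD1, a thioredoxin reductase, 1.64-fold higher. Of 24 NF-kB targets 14 fell, 3 rose and 7 did not pass, or 15 and 3 when adjusted over the list alone (camera adjusted p = 0.00813, adjusted p = 0.55 with an estimated correlation). The list included NFKB2, a subunit of NF-kB (1.25-fold lower), and ICAM1, an adhesion molecule (1.81-fold lower). Of 22 sterol genes 14 rose, 1 fell and 7 did not pass, or 16 and 1 when adjusted over the list alone (camera adjusted p = 0.000244, adjusted p = 0.55 with an estimated correlation). Members included SREBF2, a regulator of sterol genes (1.25-fold), and EBP (1.34-fold). Interferon-stimulated genes were not called (16 higher, 7 lower and 6 not passed of 29, camera adjusted p = 0.216), and the other 19 lists were not called either (0.0749 to 0.984).

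Genes changed in KO were set against the same genes after rescue. Of the 13996 genes changed in KO against WT, 7756 (55.4%) changed the opposite way with guanosine, 7211 (51.5%) with unlocalised IMPDH2, 7324 (52.3%) with the nuclear form and 6580 (47%) with the cytosolic form. Changes further from WT were fewer, with 1479 genes (10.6%) for guanosine, 1247 (8.9%) for unlocalised IMPDH2, 1384 (9.9%) for the nuclear and 1689 (12.1%) for the cytosolic form. Independent lists would share 3954, 3555, 3712 and 3544 genes with opposite changes and 3957, 3554, 3713 and 3545 with changes further from WT, in the same order. Simulations with unchanged rescued groups gave 0% for both in each of 10 runs, which is chance with no effect and leaves out what shared controls add to real effects. The 3 KO libraries entered both sides of each comparison and could not be divided between them, so part of an excess may come from the shared controls. Opposite changes of at least 2-fold on both sides were fewer, 648 or 14.8% of the 4376 genes changed at least 2-fold for unlocalised IMPDH2. Independent lists would share 115 such genes. At this minimum 50 genes changed further from WT, where independent lists would share 102. Of the 13996 genes 10445 (74.6%) were still changed the same way between KO with unlocalised IMPDH2 and WT, against a mean of 93.89% in 10 simulations without an effect of rescue. KO with unlocalised IMPDH2 differed from WT in 12417 genes, 2867 of them by at least 2-fold, and KO with guanosine differed from WT in 12307 genes, 2791 by at least 2-fold. In these comparisons with WT, IMPDH2 was 1.67-fold higher with the enzyme given back and 14.4-fold lower with guanosine. IMPDH1 was 1.2-fold higher with IMPDH2, and with guanosine it had a log2 fold change of 0.07 ± 0.033 SE that did not pass (adjusted p = 0.0615 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). This result for IMPDH1 passed in the same test with DESeq2 size factors (Benjamini-Hochberg adjusted p = 0.033) and without WT replicate 1 (0.0167), guanosine replicate 1 (0.0152) or guanosine replicate 3 (0.0273).

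**Figure D4:**
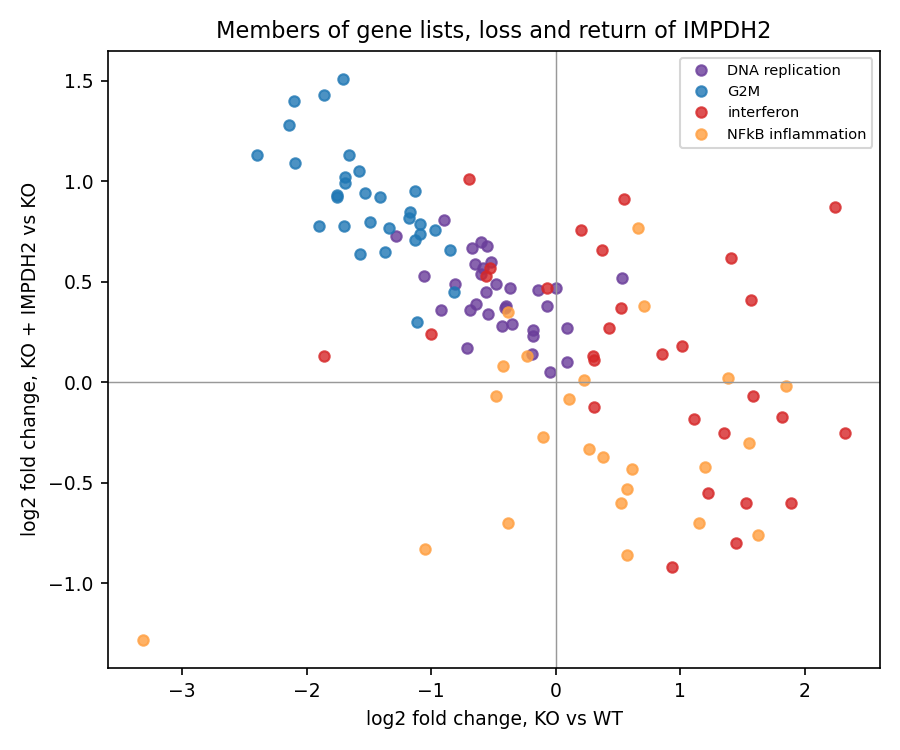
Log2 fold change in KO against WT (x axis) and in KO with unlocalised IMPDH2 against KO (y axis), 1 point per tested member of 4 gene lists; the axes share the KO libraries. The G2/M members lie in the upper left, with 30 lower in KO and 30 higher with IMPDH2.

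The nuclear form was compared with KO to ask what IMPDH2 restored from the nucleus. All 30 mitotic and 33 replication genes, 22 of 25 recombination and 18 of 30 damage signalling genes rose, and 18 of 24 NF-kB targets fell. With an estimated correlation the recombination, damage signalling and NF-kB lists were no longer called (camera adjusted p = 0.0955, 0.552 and 0.128). CCL2, a monocyte chemokine and the 1 NF-kB target that rose, went from 2.08 ± 0.159 to 17.4 ± 2.57 CPM (8.34-fold). MALL was 7.72-fold higher, NEGR1 4.03-fold, NUP210, a nuclear pore glycoprotein, 3.77-fold (9.11 ± 0.715 against 2.41 ± 0.232 CPM), PDE8B, a cAMP phosphodiesterase, 3.66-fold, HMMR 3.42-fold and DCLK1, a doublecortin-like kinase, 3.12-fold higher. The largest falls were TMPRSS15, which encodes enteropeptidase (0.383 ± 0.067 against 3.53 ± 0.436 CPM, 9.1-fold), IL2RG (8.03-fold), SERPINB2, a plasminogen activator inhibitor (6.15-fold), EPHB1 (5.79-fold), VNN1, a pantetheinase (5.33-fold), and PTPRR (4.4-fold). MAGEA6 (22.7-fold lower), DCAF8L1 (17.4-fold lower), PRSS2 (4.57-fold lower) and EIF3CL (4.95-fold higher) have close paralogs and are uncertain. ENSG00000290315 (45.4-fold higher) overlaps IMPDH2, may share reads with it and is uncertain too. EIF3CL no longer passed without KO replicate 1 (adjusted p = 0.076), KO replicate 2 (0.0566) or nuclear replicate 3 (0.098) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In all 10213 genes changed, 5033 higher and 5180 lower, and 1156 by at least 2-fold (287 higher, 869 lower). With DESeq2 size factors 5219 were higher and 4986 lower, and for coding genes alone 4783 and 3979. PARP1 rose to 377.5 ± 8.55 CPM (1.39-fold). IMPDH1 was 1.06-fold higher (adjusted p = 0.0251 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), a call that ended without KO replicate 2 (0.0599), KO replicate 3 (0.0638), nuclear replicate 1 (0.0742) or nuclear replicate 2 (0.081).

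With the nuclear form all 30 G2/M genes rose (median log2 fold change 0.95, camera adjusted p = 3.94e-25, adjusted p = 0.0399 with an estimated correlation) and all 33 DNA replication genes rose (camera adjusted p = 2.9e-17, adjusted p = 0.0329 with an estimated correlation), both in the same numbers when adjusted over the list alone. BIRC5 was 2.37-fold higher, PLK1 2.66-fold, MCM5 1.64-fold and PCNA, the sliding clamp, 1.89-fold. Of 25 homologous recombination genes 22 rose, 1 fell and 2 did not pass, with 22 and 1 when adjusted over the list alone (camera adjusted p = 1.71e-08, adjusted p = 0.0955 with an estimated correlation). Examples were RAD54L (1.79-fold) and FANCA (1.76-fold). Of 30 damage signalling genes 18 rose, 6 fell and 6 did not pass, with 18 and 6 when adjusted over the list alone (camera adjusted p = 0.0117, adjusted p = 0.552 with an estimated correlation). The list included WEE1 (1.61-fold) and CLSPN (1.62-fold). Nucleotide synthesis lists were called as well: 12 of 21 purine synthesis genes rose, 2 fell and 7 did not pass (camera adjusted p = 0.0117, adjusted p = 0.535 with an estimated correlation), and 12 of 18 pyrimidine and deoxynucleotide genes rose, 2 fell and 4 did not pass (camera adjusted p = 0.0015, adjusted p = 0.317 with an estimated correlation), with the same counts when adjusted over the list alone. SHMT1, a serine hydroxymethyltransferase, was 1.62-fold higher, PRPS2, which makes the sugar donor of purines, 1.43-fold, GMPS, which acts just after IMPDH2, 1.35-fold, and RRM2 1.85-fold higher.

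Of 24 NF-kB targets 18 fell with the nuclear form, 1 rose and 5 did not pass, with 18 and 1 when adjusted over the list alone (camera adjusted p = 1.99e-06, adjusted p = 0.128 with an estimated correlation). Members included NFKB2 (1.48-fold lower), ICAM1 (2.78-fold lower) and CXCL8, which encodes interleukin 8 (2.77-fold lower). Of 20 NRF2 targets 16 rose, 2 fell and 2 did not pass, or 17 and 2 when adjusted over the list alone (camera adjusted p = 3.89e-05, adjusted p = 0.128 with an estimated correlation). Examples were TXNRD1 (1.58-fold) and NQO1 (2.19-fold). Of 22 sterol genes 14 rose, 2 fell and 6 did not pass, with 14 and 2 when adjusted over the list alone (camera adjusted p = 0.0186, adjusted p = 0.653 with an estimated correlation). An example was SREBF2 (1.22-fold). Of 13 mitochondrially encoded genes 10 rose, 1 fell and 2 did not pass, with 10 and 1 when adjusted over the list alone (camera adjusted p = 0.0277, adjusted p = 0.774 with an estimated correlation). An example was MT-ND4 (1.24-fold), while the mitochondrial share was 7.67% ± 0.13 against 7.72% ± 0.17 in KO. The other 17 lists were not called (camera adjusted p 0.136 to 0.965), among them the PARP list with 10 higher, 5 lower and 8 not passed of 23.

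The cytosolic form was compared with KO in the same way. Every one of 30 mitotic and 33 replication genes, 22 of 25 recombination, 18 of 30 damage signalling and 18 of 20 NRF2 target genes rose, and 21 of 24 NF-kB targets and 15 of 29 interferon-stimulated genes fell. With an estimated correlation the damage signalling and interferon lists were no longer called (camera adjusted p = 0.383 and 0.246). Besides the overlapping locus ENSG00000290315 (57.2-fold, uncertain), DCLK1 rose from 3.46 ± 0.41 to 22.4 ± 1.12 CPM (6.47-fold), MALL 5.56-fold, PIK3CG, a phosphoinositide kinase, 4.66-fold, NEGR1 4.42-fold, ID1, a transcriptional inhibitor, 4.03-fold and SLC7A11, the cystine transporter, 3.43-fold (240 ± 10 against 70.1 ± 6.59 CPM). CCL2 fell from 2.08 ± 0.159 to 0.173 ± 0.0521 CPM (11.6-fold), IL2RG 7.51-fold, CMKLR1, the chemerin receptor, 6.73-fold, PI3, which encodes the elastase inhibitor elafin, 5.91-fold and PGF, placental growth factor, 5.5-fold. MAGEA6, PRSS2 and the cystatins CST1, CST2 and CST4, 7.34-fold, 7.66-fold and 6.47-fold lower, have close paralogs and are uncertain. In all 9751 genes changed, 4741 higher and 5010 lower, and 1062 by at least 2-fold (239 higher, 823 lower). DESeq2 size factors gave 4992 higher and 4731 lower, and coding genes alone 4479 and 4079. PARP1 rose to 363.8 ± 10.9 CPM (1.34-fold), and IMPDH1 did not pass (log2 fold change 0 ± 0.032 SE, adjusted p = 0.988 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

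With the cytosolic form all 30 G2/M genes (median log2 fold change 0.86, camera adjusted p = 1.63e-26) and all 33 DNA replication genes (camera adjusted p = 1.42e-18) rose, in the same numbers when adjusted over the list alone, and adjusted p = 0.0221 with an estimated correlation for each list. BIRC5 was 2.12-fold higher, PLK1 2.39-fold, MCM5 1.56-fold and MCM4 1.42-fold. Of 25 homologous recombination genes 22 rose, 1 fell and 2 did not pass, with 22 and 1 when adjusted over the list alone (camera adjusted p = 6.74e-10, adjusted p = 0.0384 with an estimated correlation). Examples were FANCM (1.61-fold) and RAD54L (1.69-fold). Of 30 damage signalling genes 18 rose, 6 fell and 6 did not pass, with 18 and 6 when adjusted over the list alone (camera adjusted p = 0.0105, adjusted p = 0.383 with an estimated correlation). The list included WEE1 (1.64-fold) and CLSPN (1.72-fold). Purine synthesis (11 higher, 3 lower and 7 not passed of 21, camera adjusted p = 0.00448) and pyrimidine and deoxynucleotide genes (11 higher, 3 lower and 4 not passed of 18, camera adjusted p = 0.00409) were called, with the same counts when adjusted over the list alone and adjusted p = 0.316 with an estimated correlation for each. MTHFD1, a folate enzyme, was 1.42-fold higher and RRM2 2.03-fold higher. Of 12 replication histone genes 9 rose and 3 did not pass, with 9 when adjusted over the list alone (camera adjusted p = 0.00251, adjusted p = 0.161 with an estimated correlation). Members included H2BC12 (1.86-fold) and H1-2 (2-fold). These mRNAs lack a poly(A) tail, so their level also depends on how the libraries were selected.

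Of 20 NRF2 targets 18 rose with the cytosolic form and 2 did not pass, with 18 when adjusted over the list alone (camera adjusted p = 1.94e-10, adjusted p = 0.0221 with an estimated correlation). Examples were NQO1 (294 ± 18.7 against 94.7 ± 4.94 CPM, 3.11-fold) and TXNRD1 (1.85-fold). Of 24 NF-kB targets 21 fell, 1 rose and 2 did not pass, with 21 and 1 when adjusted over the list alone (camera adjusted p = 2.45e-10, adjusted p = 0.0329 with an estimated correlation). The list included ICAM1 (4.95-fold lower) and NFKB2 (1.59-fold lower). Of 29 interferon-stimulated genes 15 fell, 4 rose and 10 did not pass, or 16 and 4 when adjusted over the list alone (camera adjusted p = 0.00209, adjusted p = 0.246 with an estimated correlation). Members included IFI27 (2.31-fold lower) and BST2 (1.7-fold lower). Of 13 mitochondrially encoded genes 8 rose, 2 fell and 3 did not pass, or 10 and 2 when adjusted over the list alone (camera adjusted p = 0.00911, adjusted p = 0.522 with an estimated correlation). An example was MT-ND4 (1.29-fold), with a mitochondrial share of 7.69% ± 0.23. The other 16 lists were not called (camera adjusted p 0.0757 to 0.969). The responses to the nuclear and cytosolic forms overlapped: 3811 genes rose and 3746 fell with both, where 1239 and 1348 would be shared by independent lists, and 208 moved in opposite directions. Across the 19252 genes, which are not independent replicates, their log2 fold changes had r = 0.644, against a mean of 0.503 and a maximum of 0.552 in 10 simulations with no effect and the same shared KO libraries. The covariance was 0.342 against a simulated 0.077, a difference of 0.265, and part of the excess may come from the shared controls, which cannot be split.

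The direct comparison of the nuclear with the cytosolic form tests whether their effects differ. Higher with the nuclear form were 19 of 29 interferon-stimulated genes, 8 of 17 luminal markers and 13 of 22 sterol genes, and lower were 10 of 20 NRF2 targets, 17 of 29 ATF4 response genes and 7 of 12 replication histone genes. With an estimated correlation the sterol list was no longer called (camera adjusted p = 0.147). CCL2 was 96.9-fold higher with the nuclear form (17.4 ± 2.57 against 0.173 ± 0.0521 CPM, log2 fold change 6.6 ± 0.178 SE, adjusted p = 1.39e-13 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), CMKLR1 9.85-fold, SPOCK1, a matrix proteoglycan, 5-fold, TIE1, an endothelial receptor kinase, 4.32-fold (10.5 ± 0.459 against 2.44 ± 0.0989 CPM), CYRIA, a Rac1 interactor, 3.78-fold and NUP210 3.53-fold. HLA-DOA, an antigen presentation gene, was 3.6-fold higher, a call that ended with an offset for transcript length (adjusted p = 0.298, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Lower with the nuclear form were SERPINB2 (9.22-fold), SELENBP1, a selenium binding protein (3.61-fold), DHRS2, a short-chain dehydrogenase (3.45-fold), TMPRSS15 (3.37-fold), MMP3, the stromelysin protease (32.4 ± 5.61 against 109 ± 15.5 CPM, 3.36-fold), and IL13RA2 (3-fold). ALPP, CST1, CST4, DCAF8L1, KRTAP2-3 and MAGEA6 are also among the largest differences, and their close paralogs make them uncertain. In all 4600 genes differed, 2571 higher and 2029 lower, 334 of them by at least 2-fold (185 higher, 149 lower), and 1855 with an offset for transcript length. IMPDH2 itself was lower with the nuclear form (log2 fold change -0.35), IMPDH1 was 1.06-fold higher, a call that ended in most alternatives, and PARP1 did not pass (log2 fold change 0.05 ± 0.026 SE, adjusted p = 0.155 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

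Of 29 interferon-stimulated genes 19 were higher with the nuclear than with the cytosolic form, 3 lower and 7 did not pass, or 19 and 4 when adjusted over the list alone (camera adjusted p = 6.11e-09, adjusted p = 0.0253 with an estimated correlation). The list included OAS3 and OAS1, oligoadenylate synthases (1.6-fold and 2.68-fold), and DDX60, a helicase (1.85-fold). Of 23 PARP and ADP-ribosylation genes 8 were higher, 1 lower and 14 did not pass, or 9 and 1 when adjusted over the list alone (camera adjusted p = 0.00276, adjusted p = 0.0253 with an estimated correlation). The members with the smallest adjusted p were PARP4 (1.16-fold), PARP12 (1.39-fold), PARP14 (1.25-fold) and PARP9 (1.35-fold), of which PARP9, PARP12 and PARP14 also respond to interferon. Of 24 NF-kB targets 11 were higher, 3 lower and 10 did not pass, or 12 and 3 when adjusted over the list alone (camera adjusted p = 0.0341, adjusted p = 0.592 with an estimated correlation). Members included CCL2 and ICAM1 (1.78-fold). Of 22 sterol genes 13 were higher and 9 did not pass, or 16 higher when adjusted over the list alone (camera adjusted p = 2.24e-07, adjusted p = 0.147 with an estimated correlation). Examples were SREBF2 (1.19-fold) and FDFT1, squalene synthase (1.23-fold). Of 17 luminal and epithelial markers 8 were higher, 1 lower and 8 did not pass, or 9 and 1 when adjusted over the list alone (camera adjusted p = 0.000222, adjusted p = 0.0169 with an estimated correlation). The list included CLDN4 (15.5 ± 1.09 against 8.21 ± 0.819 CPM) and SPDEF, an epithelial transcription factor (2.51-fold). Of 30 G2/M genes 11 were higher, 2 lower and 17 did not pass, or 14 and 3 when adjusted over the list alone (camera adjusted p = 0.0223, adjusted p = 0.833 with an estimated correlation). HMMR was 1.31-fold higher, BIRC5 and PLK1 were each 1.12-fold higher, and neither BIRC5 nor PLK1 passed with an offset for transcript length.

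Of 20 NRF2 targets 10 were lower with the nuclear form, 1 higher and 9 did not pass, or 11 and 1 when adjusted over the list alone (camera adjusted p = 1.56e-07, adjusted p = 0.0329 with an estimated correlation). Members included the ferritin genes FTL and FTH1 (1.56-fold and 1.34-fold lower) and NQO1 (1.42-fold lower). Of 29 ATF4 response genes 17 were lower, 2 higher and 10 did not pass, or 19 and 2 when adjusted over the list alone (camera adjusted p = 1.56e-07, adjusted p = 0.0144 with an estimated correlation). Examples were SLC3A2 and SLC7A5, the chains of an amino acid transporter (1.49-fold and 1.39-fold lower). Of 12 replication histone genes 7 were lower and 5 did not pass, or 9 lower when adjusted over the list alone (camera adjusted p = 1.48e-07, adjusted p = 0.0169 with an estimated correlation). The list included H1-2 (2.04-fold lower) and H2BC12 (1.74-fold lower). Of 18 unfolded protein response genes 7 were lower, 2 higher and 9 did not pass, with 7 and 2 when adjusted over the list alone (camera adjusted p = 0.00782, adjusted p = 0.435 with an estimated correlation). Members included HSPA5, the chaperone BiP (1.24-fold lower), and CALR, which encodes calreticulin (1.2-fold lower). The other 17 lists were not called (camera adjusted p 0.0747 to 0.892). Among them 5 of 25 homologous recombination genes, 5 of 30 damage signalling genes and 8 of 33 DNA replication genes differed between the forms. Against unlocalised IMPDH2, 2301 genes differed with the nuclear form and 4661 with the cytosolic form, 107 and 230 of them by at least 2-fold. With an offset for transcript length 563 and 1715 differed, and the count for the nuclear form fell to 1460 without unlocalised replicate 1. IMPDH2 was 1.79-fold and 1.41-fold lower than with the unlocalised form, and IMPDH1 did not pass in either comparison (log2 fold change 0.04 and -0.05).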

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

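Tests of reads shared between overlapping genes, of QRICH1 transcription, of IMPDH2 dose and of a single library that stands apart were chosen after the results were seen. The tests of copy number, of a few abundant genes and of other splits of the samples were chosen before them.

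All 5 knockout-derived groups shared changes of at least 2-fold against WT in 1624 genes, 753 higher and 871 lower, whether or not IMPDH2 or guanosine was supplied. Copy number differences between the WT and knockout cells are likely to account for part of this: window medians of KO with unlocalised IMPDH2 against WT spread 4.11 times as widely as under shuffled positions, against 1.25 to 3.08 among knockout-derived groups. The SD of these medians was 0.281 against WT, and 0.048 to 0.074 among knockout-derived groups. Of the 26 windows shifted by at least 0.5 on the log2 scale 25 were lower. The shifted windows hold 1346 of all 11703 genes in windows (11.5%). They hold 201 of the 613 shared genes that lie in windows (32.8%) in the same direction and 17 in the opposite one. The windows were picked by the shift of genes that include these, however, and only 1 was higher. A run of 7 genes on chromosome 8 (406428 to 4994972, GRCh38), including ARHGEF10, was at most 1% of WT in KO. A few abundant genes taking more of the counts were allowed for by TMM scaling in every fit. A fit without 33 such genes gave 1613 shared genes, 1610 of them shared in the same direction in the fit of all genes. That fit was scaled in the same way and could hardly differ, so it does not decide. The scaling itself moved log2 fold changes against WT by 0.161 for KO, 0.081 with unlocalised IMPDH2 and 0.096 with guanosine, where shared genes needed at least 1. Effects of IMPDH2 loss that reconstitution did not undo were not tested apart from other differences between the knockout cells and WT.

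QRICH1 fell from 93.4 CPM in KO to 11.1 with unlocalised IMPDH2 while the locus that overlaps both QRICH1 and IMPDH2 rose from 3.4 to 226.7. Reads shared between overlapping genes may contribute and stay open: QRICH1 plus the locus in the reconstituted line stood at 2.55 times QRICH1 in KO, but the locus may also take IMPDH2 reads, so this sum does not decide. Lower QRICH1 transcription stays open too, since of the 6 QRICH1 transcripts at 1 CPM or more in KO, 1 was at or above its KO level with unlocalised IMPDH2. Transcript levels here used library totals without TMM scaling.

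The nuclear and cytosolic IMPDH2 lines differed in 4600 genes. A dose effect that keeps growing with IMPDH2 mRNA is argued against as the account of most of the genes at least 2-fold apart. Of these 334 genes, the unlocalised line, with the most IMPDH2 mRNA, lay beyond the cytosolic line for 24 (7.2%, 95% interval 4.7 to 10.5). Picking genes by the cytosolic line itself lowers this share, by an amount that was not computed. A growing dose as a smaller part of the difference and a dose effect that levels off therefore stay open. The interval treats genes as independent, which they are not. A single cytosolic library that stands apart is argued against, since 4186 genes differed without cytosolic replicate 3. Copy number differences between the reconstituted lines could contribute and stay open, with a ratio of 2.58. The median over the 397 genes of chromosome 14 was 0.245 for the cytosolic line against KO and 0.205 against the unlocalised line. For nuclear against cytosolic it was -0.149. The lowest window medians for nuclear against cytosolic were -0.26, in neighbouring windows of chromosome 4. The nuclear line differed regionally from the unlocalised line too, with a ratio of 3.08. Window medians of the nuclear against the unlocalised line included -0.17 on chromosome 19, 0.16 on chromosome 13 and -0.16 on chromosome 4. These regional differences were small, with an SD of window medians of 0.048, against 0.281 for the unlocalised line against WT. An effect of the location of the enzyme was not told apart from differences between lines.

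Against KO 208 genes moved in opposite directions, and those looked at again were the 9 coding genes with an average log2 CPM of at least 1 that passed and moved by at least 0.5 on the log2 scale each way. They were CCL2 (nuclear minus cytosolic log2 fold change 6.6), SPOCK1 (2.32), TIE1 (2.11), HLA-DOA (1.85), GNAO1 (1.71), SLC14A1 (1.69), KRTAP2-3 (-1.54, uncertain for its paralogs), PLAAT4 (1.27) and DAAM2 (1.22). The share of counts on lncRNA transcripts was 1.71% in KO against 1.231% in WT, and was higher in every KO library.

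In each comparison of 3 against 3 libraries, 10 splits are too few for a share under 0.05. Every other split mixes libraries of both groups, so it keeps part of their difference and has a wider spread. Its counts of genes and lists are therefore not values without an effect. The real split was the only 1 of 10 with as many changed genes in all 10 comparisons: 13475 against at most 0 in another split for KO against WT, 10666 and 0 for guanosine, 9585 and 0 for unlocalised, 9974 and 0 for nuclear and 8861 and 0 for cytosolic IMPDH2 against KO, and 3648 and 3 for nuclear against cytosolic. For the secondary comparisons the values were 12098 and 0 for unlocalised IMPDH2 and 11986 and 0 for guanosine against WT, and 2504 and 3 for nuclear and 3756 and 2 for cytosolic against unlocalised IMPDH2. Called lists were 11 in the real split and at most 9 in another for KO against WT, 11 and 9 for cytosolic IMPDH2 against KO and 9 and 7 for nuclear against cytosolic, with 1 split as large in each. They were 9 and 9 for guanosine, 7 and 7 for unlocalised and 10 and 10 for nuclear IMPDH2 against KO, with 2 splits as large in each. Since the other splits are mixtures, these list counts do not decide whether the groups differ.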

How the results depend on the processing

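No test in this part was chosen after its result was seen, except PARP1, IMPDH2 with the overlapping locus, coding genes alone and the subtracted window medians. Of 374 single gene results 362 kept their direction and call in every alternative that was run on single genes. The minimum fold change, coding genes alone and the series count table were not run on them, and a missing adjusted p counted as kept. Most of these genes were picked for a large fold or a small adjusted p, which favours keeping a call. The 12 exceptions were IMPDH1 in 4 comparisons and EIF3CL, MAGEA6, CACNA2D4, HLA-DOA, BIRC5, PLK1, MKI67 and PARP1 in 1 each. With a log2 fold change of at least 1 the counts were 4376 for KO against WT, 1481 for guanosine, 955 for unlocalised, 1156 for nuclear and 1062 for cytosolic IMPDH2 against KO, 334 for nuclear against cytosolic, 2867 and 2791 for unlocalised IMPDH2 and guanosine against WT, and 107 and 230 for nuclear and cytosolic against unlocalised. With an average transcript length offset 6511 genes changed for unlocalised IMPDH2 against KO, 1855 for nuclear against cytosolic, and 563 and 1715 for nuclear and cytosolic against unlocalised IMPDH2, and the cause was not tested. With the replicate block the counts were 13955, 10799, 9663, 10069, 9599, 4425, 12333, 12221, 2153 and 4506 in the same order of comparisons, but replicate numbers do not pair between groups (correlations -0.086 to 0.142, with 7 of 18 libraries closest to 1 of their own number).

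With 1 library left out in turn, changed genes ranged from 13547 to 13641 for KO against WT, 10132 to 10273 for guanosine, 8898 to 9139 for unlocalised, 9387 to 9539 for nuclear and 8884 to 9383 for cytosolic IMPDH2 against KO, 3590 to 4186 for nuclear against cytosolic, 11806 to 11980 and 11709 to 11907 for unlocalised IMPDH2 and guanosine against WT, and 3510 to 4711 for cytosolic against unlocalised. For nuclear against unlocalised IMPDH2 they ranged from 1460 (without unlocalised replicate 1) to 1703, with 1504 without unlocalised replicate 2 and 1474 without nuclear replicate 1. Called lists ranged from 11 to 11, 9 to 11, 7 to 8, 8 to 10, 11 to 12 and 9 to 10 in the 6 main comparisons. Over all these runs 5 single list calls were lost and 8 were gained, while 959 results stayed. Camera with an estimated correlation called 0, 4, 3, 2, 5 and 6 lists, and fry called 26, 19, 21, 24 and 21 in the first 5. Without a filter on low counts 15 lists were called for unlocalised IMPDH2 against KO. Fry reversed purine salvage (adjusted p = 1.5e-05) and NAD metabolism (adjusted p = 0.00569) in KO against WT, neither called by camera.

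Which direction held more genes turned from lower to higher without a filter on low counts for guanosine (5520 higher, 5196 lower), nuclear (5165, 4755) and cytosolic IMPDH2 (4889, 4598) against KO, and with the DESeq2 Wald test (5286 and 4912, 4954 and 4571, 4785 and 4329). It turned for KO against WT with the length offset (6132 higher, 5909 lower) and without a filter for unlocalised IMPDH2 (6373, 6240) and guanosine (6278, 6194) against WT, and in some fits of the 6 compared samples alone or without 1 library.

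IMPDH2 in KO stood at 13.5% of WT in TPM and 11.5% with the overlapping locus added. The values of single transcripts that follow used library totals without TMM scaling. Single transcripts stood at 3% (IMPDH2-211), 6.1% (IMPDH2-201), 35.2% (IMPDH2-207), 57.2% (IMPDH2-235), 1.5% (IMPDH2-202), 0% (IMPDH2-204), 10.3% (IMPDH2-217), 15% (IMPDH2-230) and 12.3% (IMPDH2-234), and 4 others at 0%, 16.7%, 19.7% and 146.4%. The 57.2% rests on KO replicate 1, with 26.56 CPM against 0 in both other KO libraries. IMPDH2-203 and IMPDH2-228, under 1 CPM in WT, were at 6.17 ± 6.36 CPM in KO against 0.91 ± 0.32 and at 1.13 ± 1.07 against 0.39 ± 0.68. The return towards WT with unlocalised IMPDH2 was 14.8% when 2-fold changes were required on both sides. This was 648 genes, where independent lists would share 115. Depth limits genes at or near 0, where the fold is a bound, and the cause of moved counts was not tested.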

Other observations

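Expression lost with neighbouring genes stood out in the knockout cells. The run on chromosome 8 held FBXO25, TDRP, ERICH1, CLN8, ARHGEF10, MYOM2 and CSMD1, and the next expressed gene, MCPH1 (6406592, GRCh38), stood at 10.6 CPM in WT and 10.8 in KO. The window at 135520643 to 156025710 on the X chromosome had a median log2 fold change of -0.94 in KO against WT, and on that chromosome 12 coding genes were among those lost and 16 among those gained, so the window does not stand for all of it. PAGE5 (ratio 1420, interval 392 to 11700), 1 of those lost, starts at 55220355, outside that window. Among the 1624 shared genes 37 coding genes were at most 3 counts in each knockout-derived group and 49 were at most 3 counts in WT. This pattern, with a window ratio of 4.11, is in line with knockout cells that descend from few cells and may differ from WT in more than IMPDH2.

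All 30 G2/M genes were lower in KO than in WT and higher in each of the 4 rescued groups than in KO. These 5 comparisons use the same 3 KO libraries, which were not divided between them, and no simulation was made for this list alone. Over all genes changed in KO against WT, simulations with unchanged rescued groups gave 0% opposite calls in each of 10 runs. This argues against replicate spread of the shared KO libraries as the sole source of the agreement. Simulated genes were independent of one another, so a state common to the 3 KO libraries is not covered. Interferon-stimulated genes had a median log2 fold change against KO of -0.67 with guanosine, 0.14 with unlocalised, 0.15 with nuclear and -0.21 with cytosolic IMPDH2, and between rescued groups the list was tested only for nuclear against cytosolic IMPDH2. Among genes with an average log2 CPM of at least 3, which are 10615 and not independent replicates, the nuclear and cytosolic responses had r = 0.872, against a simulated mean of 0.487 and a maximum of 0.652.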
